A study of Drosophila melanogaster with 23 samples.

How the data were processed

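The samples were pools of whole Drosophila melanogaster larvae at stage L1, male and female together. Per the labels' protocols, embryos from crosses kept at 25 °C were laid on grape-juice agar, 25-30 larvae per sample were collected in Trizol, and RNA was cleaned on a Zymo column with DNase I digestion. Total RNA libraries were made with the Nugen Ovation Universal Drosophila kit and sequenced as paired ends of 100 bp. Per the submitters' processing notes, STAR 2.7.2a and Subread 2.0.3 were used. The genome build, the gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here, so values of near-identical or overlapping genes (Hsp70 and Stellate copies, histone repeats) are uncertain.

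The deposited values were read counts per gene, a table of whole numbers for 17606 FlyBase gene identifiers in 23 libraries. Among counts from 5 to below 20, 62.1% were even numbers, against 49.91% of counts from 1000 up; what made small counts even is not given. Ends of a pair counted apart for most genes may do so, which was not tested. Library totals, the minimum count and the chi-square against counting error would then refer to read ends and not to fragments. The submitters dropped replicate 1 of yw because of a library construction error, so yw had 3 libraries and the other 5 groups had 4 each. The sum of counts per library ran from 111138070 to 157973821. The labels do not say that replicates are independent beyond being separate samples, so the p-values measure the spread between samples, part of which may be technical. Replicate libraries of every group differed by more than counting error, with a chi-square per degree of freedom of at least 20.0 for each pair.

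Gene names, biotypes and positions came from the BDGP6.54 annotation by gene identifier, which matched 17527 of the 17606 identifiers (99.55%). Positions are those of that annotation, not of the build used for the counts.

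Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 14365 genes (2249 on the X, 11851 on the arms of chromosomes 2 and 3, 111 on arm 4, 43 on the Y) and removed 3241. Library sizes were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 23 libraries together in edgeR 4.0.16 under R 4.3.3 with robust dispersions, which left 17 residual degrees of freedom. The common biological coefficient of variation was 0.311. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene was called at an adjusted p below 0.05. Expression is given as CPM, counts scaled to a common library total with the TMM factors, as mean ± SD over libraries, and log2 fold changes as estimate ± SE.

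There were 5 comparisons: the Set2 mutant against yw, and, against the histone control, combined H3K36R, H3.3K36R alone and H4K16R, then combined H3K36R against H3.3K36R alone. A pair of differences between effects was tested gene by gene as contrasts of the same model. For each library an X minus autosome index was computed as the mean log2 CPM (prior count 2) of X genes minus that of genes on arms 2L, 2R, 3L and 3R. Group differences in the index had a two-sided exact permutation test, adjusted over the 5 comparisons. With 4 libraries against 4, or 4 against 3, the smallest p that test can give is 0.0286.

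Gene lists, 35 in number, were fixed before the data were examined, as were the comparisons, the tests, the thresholds and the rule for named genes. They covered the dosage compensation (MSL) complex and roX RNAs; H3K36 writers, erasers and readers; the H4K16 acetyltransferase NSL complex; replication-dependent histones; histone variants and histone mRNA processing; Hox genes and other Polycomb and Trithorax targets; the Polycomb group; and heterochromatin with fourth-chromosome factors. They further covered ribosomal proteins; the nuclear genes of the mitochondrial respiratory chain; mitochondrially encoded genes; heat shock; antimicrobial and immune effectors; oxidative stress and detoxification; apoptosis and p53 response; DNA replication and cell cycle; ecdysone; cuticle proteins; chitin and epidermal barrier; midgut digestive enzymes; fat body and storage; and glycolysis. The rest were markers of neurons, glia, muscle, hemocytes, trachea with salivary gland, and Malpighian tubule with oenocytes and nephrocytes; female and general germline; testis-specific genes; Y-linked genes; sex determination; yolk, chorion and maternal egg products; nucleolus and ribosome biogenesis; and signalling targets of growth and patterning. Lists with at least 3 tested genes (34 of the 35) were tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and comparisons. They were tested again with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Chromosome arms were tested the same way. The mean log2 CPM of each arm minus that of the other tested genes also had an exact permutation test over libraries. It was adjusted over all arms and comparisons, and no arm passed, with a smallest adjusted p of 0.0714.

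The rule for named genes took 12 genes in every comparison (Set2, His3.3A, His3.3B, roX1, roX2, msl-1, msl-2, msl-3, mof, mle, y and w). It added the 8 largest rises and the 8 largest falls among called genes with a named symbol, a mean of at least 5 CPM and no overlap between the libraries of both groups, and up to 4 members of each list with the smallest adjusted p.

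Calls and the index were tested on simulated data with known changes in gene expression. Of 66 genes changed 4-fold, 52 or 53 were found in each comparison, and of 67 changed 2-fold, 32 to 41 were found. Of 67 genes changed 1.5-fold, 14 to 25 were found, and false calls were 2.59% to 5.71% of all calls. A simulated X shift of -0.2 was measured as -0.16 to -0.20. Simulated genes were drawn independently of each other, without the axis of spread that real replicates share, and few genes were changed for the calls. These rates may therefore not hold for the real libraries.

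The alternatives tried were RLE size factors, TMM factors from autosomal genes, the Wald test of DESeq2 1.42.0, other filters, a fit of each pair of groups alone, protein-coding genes alone, the replicate number as a block, other prior counts and summaries for the index, and leaving out each library in turn. After the data were seen, 3 more were added: removal of each library's trend on gene length, a covariate for the main axis of spread within histone genotypes, and leaving out the third replicates of all histone genotypes. A check of GC content was not run, since no genome sequence was at hand. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.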

Results

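RNA of pooled male and female L1 larvae was measured in 23 libraries of 6 genotypes. The genotypes were the stock yw (3 libraries), a Set2 mutant (4) and 4 histone genotypes with 4 libraries each. These were a histone control with wild-type replicated H3.2 and with H3.3 labelled as control, and H4K16R larvae with the same H3.3 label. The others were larvae with H3.3K36R alone and larvae with H3.3K36R and H3.2K36R combined. Set2 is the enzyme that trimethylates lysine 36 of histone H3 (H3K36), and H4K16 is the lysine acetylated by the dosage compensation complex on the male X. The series asks how Set2 and H3K36 act on expression of the male X chromosome, here in larvae of mixed sex. Library totals ran from 111138070 counts in H3.3K36R replicate 2 to 157973821 in Set2 replicate 2. Larvae with combined H3K36R had the lowest share of counts on mitochondrially encoded genes, 1.24% ± 0.061 (SD, n = 4), against 1.77% ± 0.32 (n = 4) in the histone control.

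Set2 itself, the gene targeted in the Set2 mutant (FBgn0030486, chromosome X, 13413242 to 13421024), was read at 4.97 to 7.69 CPM in the 4 mutant libraries and at 70.4 to 82.4 CPM in the 3 yw libraries. Its log2 fold change was -3.57 ± 0.11 (adjusted p = 1.31e-15), an 11.9-fold fall. The mean level of Set2 was 73.3 CPM in the histone control, 59.9 in H4K16R, 75.8 in H3.3K36R alone and 76.5 in combined H3K36R, and it was not called in any of those genotypes against the control. The H3.3 gene His3.3A rose in the Set2 mutant from 63.8 ± 4.73 to 122 ± 7.03 CPM (SD, n = 3 and 4), a log2 fold change of 0.94 ± 0.13 (edgeR adjusted p = 1.07e-05), while His3.3B was at 0.07. His3.3B rose in combined H3K36R by 0.32 ± 0.07 (adjusted p = 0.000402), and His3.3A was at 0.21 there without passing. The mean level of His3.3A was 34.6 CPM in the histone control, 43.1 in H4K16R, 42.1 in H3.3K36R alone and 40.1 in combined H3K36R. All were below the 63.8 CPM of yw, against which the histone genotypes were not tested, so the control may not be wild type for H3.3. Of the 111 replication-dependent histone genes in the table only 2 had enough counts to be tested, and neither was called in any comparison. The mRNA levels of the mutated histone repeats were therefore not measured here.

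**Figure D1:**
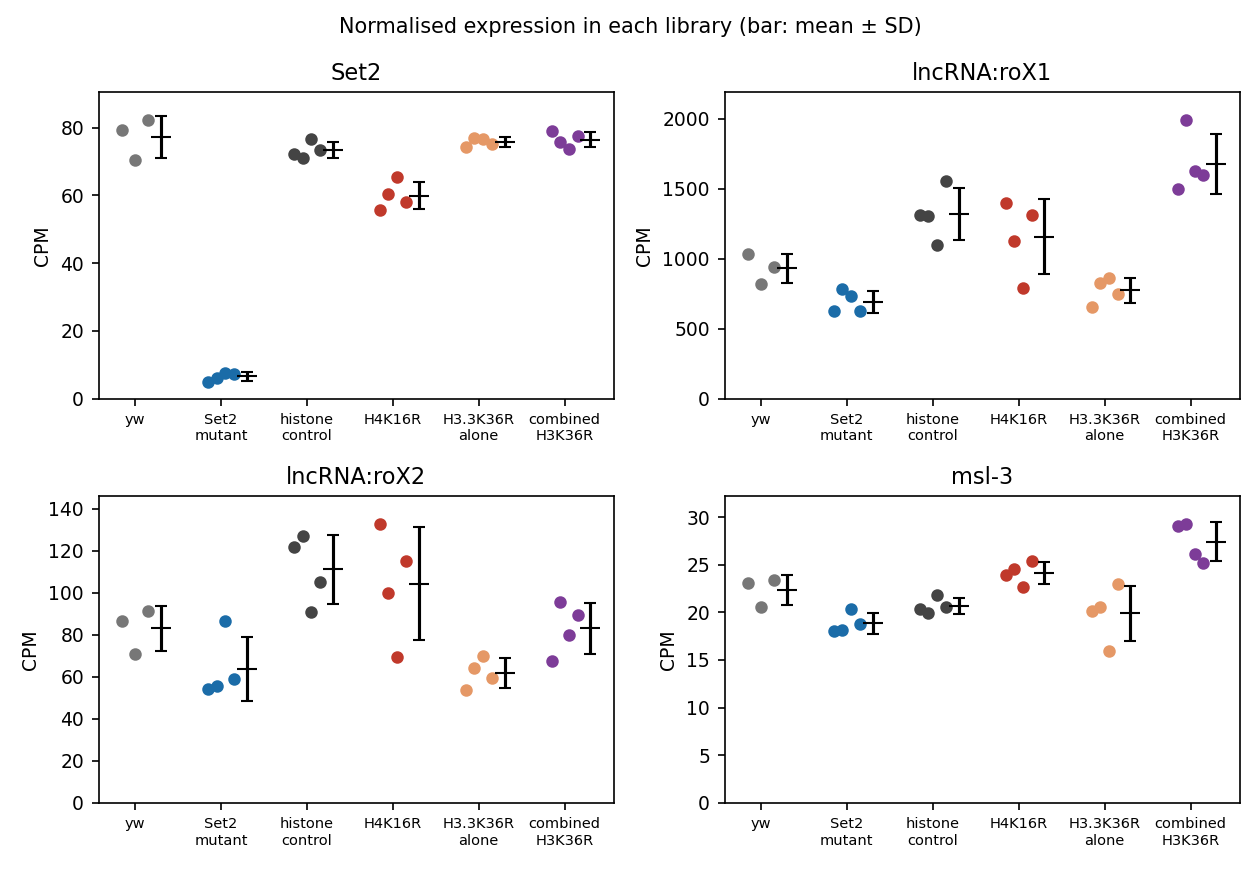
Normalised expression (CPM) of Set2, roX1, roX2 and msl-3 in each library of the 6 genotypes, with points for libraries and a bar for mean ± SD. Set2 was at 4.97 to 7.69 CPM in the Set2 mutant and roX1 was at 773 CPM in H3.3K36R alone against 1317 CPM in the histone control.

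The Set2 mutant was compared with yw to ask what loss of Set2 changes in L1 larvae, and whether X-linked genes are affected more than others. Neuronal genes were lower in the mutant as a group, with 23 of 28 lower and none higher, and glial genes followed, with 10 of 15 lower and none higher. Genes of the mitochondrial respiratory chain, of the nucleolus and of DNA replication were higher, by a median log2 fold change of 0.38, 0.67 and 0.61. The calls of all 5 lists were lost with an estimated correlation between genes (adjusted p = 0.75 to 0.916). In all, 6399 of 14365 genes were called, 3361 higher and 3038 lower, with 832 higher and 788 lower by at least 2-fold. The balance depended on the setting: 52.5% of calls were higher, but 43.6% with a covariate for the main axis of spread within the histone genotypes (1451 higher and 1878 lower) and 59.1% once each library's trend on gene length was removed. Libraries of both groups did not overlap for 46% of genes, where chance gives 5.71%. The 4 mutant libraries also stood apart on the main axis of spread within the histone genotypes, with scores of 52.8 to 70.4 against -12.2 to -5.92 in yw.

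Genes were ranked among called genes with a named symbol, a mean of at least 5 CPM and no overlap between groups, here and in the other comparisons. Besides Set2 itself, the largest falls in that set were in Lcp3, a larval cuticle protein (-4.68 ± 0.44), the small heat shock gene Hsp23 (-2.65 ± 0.35), and the kinesin gene Klp54D (-2.63 ± 0.17). They were followed by the fucosyltransferase gene FucTC (-2.58 ± 0.14), the photolyase gene phr (-2.54) and the aspartic protease gene Bace (-2.26). Pdcd4, an abundant X-linked gene, fell from 520 to 108 CPM (-2.27 ± 0.18, adjusted p = 7.57e-09). The largest rises in that set were in Jig (7.49 ± 1.37, adjusted p = 0.000371), in the cuticle gene Cpr65Eb (8.50 ± 2.51) and in the Osiris genes Osi18, Osi19, Osi9, Osi7, Osi20 and Osi6 (7.20 to 7.68), which encode membrane proteins of cuticle-forming cells. The spread of the Osiris genes between mutant libraries was as large as their mean, as for Osi7 at 722 ± 783 CPM (SD, n = 4) against 4.44 in yw. The calls of Osi6, Osi7 and Osi20 were lost without any of the yw replicates 2, 3 and 4, that of Osi6 also without Set2 replicate 1, and that of Osi19 without yw replicate 4 (adjusted p = 0.0532 to 0.0954). The cuticle protein list as a whole had 24 of 115 genes higher and 15 lower (20 and 14 adjusted over the list alone), and its test did not pass (adjusted p = 0.463).

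Among neuronal genes, Gad1, which makes the transmitter GABA, fell by 0.96 ± 0.11 on the log2 scale, the synaptic release gene unc-13 fell by 1.32 ± 0.17 and the monoamine transporter gene Vmat fell by 0.93 ± 0.12. The list had 25 lower genes adjusted over the list alone, with an adjusted p of 2.14e-11 against other genes and an adjusted p = 0.75 with an estimated correlation. Glial genes included the glutamate transporter gene Eaat1 (-1.05 ± 0.11), the glutamine synthetase gene Gs2 (-0.79 ± 0.13) and the glial regulator repo (-0.59 ± 0.10). There were 11 lower adjusted over the list alone (adjusted p = 0.00142, and adjusted p = 0.75 with an estimated correlation). In fat body and storage genes 9 of 23 were lower and none higher, among them the fatty acid synthesis genes Desat1 (-1.16), FASN1 (-1.44) and ACC (-1.03) and the growth factor gene Ilp6 (-1.22). That list passed at an adjusted p of 0.0148 and stood at an adjusted p = 0.819 with an estimated correlation. Of heat shock genes 7 of 19 were lower and 1 higher (adjusted p = 0.0205, and adjusted p = 0.75 with an estimated correlation), led by Hsp23 and by the near-identical copies Hsp70Aa (-4.07) and Hsp70Ba (-3.48). Hsp23 was uneven in yw itself, at 20.4 ± 12.3 CPM (SD, n = 3). Signalling targets had 11 of 26 lower and 1 higher, among them the JAK/STAT ligand genes upd3 (-2.62 ± 0.45) and upd2 (-3.29 ± 0.59), the JAK/STAT target Socs36E (-0.99) and the JNK target puc (-0.67). Their adjusted p was 0.00976, and 0.75 as an adjusted p with an estimated correlation.

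Of 67 nuclear genes of the respiratory chain 46 were higher and 2 lower in the Set2 mutant (46 and 3 adjusted over the list alone). Among them were the ATP synthase subunit gene ATPsynCF6 (0.92 ± 0.10) and the complex genes COX7B (0.69 ± 0.10) and ND-13B (0.81 ± 0.12). The list's adjusted p was 4.32e-06, and its adjusted p = 0.916 with an estimated correlation. Of 36 replication and cell cycle genes 18 were higher and 2 lower (21 and 2 adjusted over the list alone), such as Orc1 (1.38) and Sld5 (1.28) of replication initiation and the kinesin gene pav (0.96). Of 22 genes of the nucleolus list 17 were higher and 1 lower (19 and 1 adjusted over the list alone). The polymerase I factor gene Tif-IA was at 0.62, and Non1 was lower at -0.73. That list, matched by symbol, also holds Rrp1 (0.98), which in flies is a DNA repair gene and not a nucleolar one. Replication and nucleolus each had an adjusted p of 0.00142, with an adjusted p = 0.916 with an estimated correlation for each. Ribosomal protein genes had 25 of 88 higher and 2 lower (22 and 2 adjusted over the list alone; RpL23A at 0.38, and the variant gene RpS5b lower at -1.18). Their adjusted p was 0.00215 and their adjusted p = 0.919 with an estimated correlation. With the score on the axis of spread as a covariate the number of called genes dropped to 3329, and 21 of the 67 respiratory chain genes were higher.

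H3K36 writers, erasers and readers had 4 of 11 higher and 4 lower, with Set2 the most changed, the demethylase genes Kdm2 (-0.49 ± 0.08) and Kdm4B (-0.71 ± 0.13) lower and the reader gene MRG15 higher (0.44 ± 0.13). The list passed as lower (adjusted p = 0.0148, and adjusted p = 0.619 with an estimated correlation), with a median of -0.10 that became 0.15 once each library's trend on gene length was removed. That call includes Set2, the mutated gene itself, and the list was not tested without it. It therefore does not show that the other members fell as a group. The call of MRG15 was lost without yw replicate 4 (adjusted p = 0.0679).

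On the X, 471 genes were higher and 482 lower in the Set2 mutant. The X minus autosome index was 0.326 ± 0.048 (SD, n = 4) against 0.400 ± 0.009 in yw (SD, n = 3), a shift of -0.07 ± 0.02 that did not pass (exact permutation p = 0.0571, adjusted p = 0.0714). With a prior count of 0.5 it was -0.09 and passed. The 3 yw libraries lay at 0.392 to 0.410, and the mutant libraries at 0.256 to 0.361. The shift was -0.11, -0.06 and -0.04 in the lowest, middle and highest tercile of genes by expression. Exact permutation p was 0.0571, 0.0286 and 0.371 for these, not adjusted. Set against all other tested genes, arm 3R was at 0.07, arm 4 at -0.37 and the X at -0.07. Their exact permutation p was 0.0286, 0.0286 and 0.0571, and none passed (adjusted p = 0.0714, 0.0714 and 0.132). In the MSL complex and roX list 1 of 10 genes was higher and 3 were lower, and the list did not pass (adjusted p = 0.638). The non-coding RNA gene roX1, a part of the complex, fell from 930 ± 107 to 693 ± 79.0 CPM (-0.42 ± 0.16, adjusted p = 0.035), and roX2 was at -0.38 (adjusted p = 0.109). The female-determining gene Sxl (-0.55) and msl-3 (-0.24) fell, and the H4K16 acetyltransferase gene mof rose (0.32 ± 0.11, adjusted p = 0.0236), while msl-1, msl-2 and mle did not pass. The calls of roX1, msl-3, mof and Sxl were all lost without yw replicate 4 (adjusted p = 0.0801, 0.128, 0.162 and 0.0718) and with the axis covariate (0.455, 0.226, 0.267 and 0.149), and that of roX1 also once the length trend was removed (0.454). The roX1 call was also lost without yw replicate 2 or Set2 replicate 1 or 4 (adjusted p = 0.107 to 0.167). That of msl-3 was lost without yw replicate 2 or Set2 replicate 1, 2 or 4 (0.0948 to 0.156), and that of mof without yw replicate 3 or Set2 replicate 2 or 3 (0.0522 to 0.0696). Arm 4, which has its own chromosome-wide regulation, had 10 of 111 genes higher and 47 lower with a median of -0.28. It passed at an adjusted p of 0.000371 and an adjusted p = 0.84 with an estimated correlation.

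**Figure D2:**
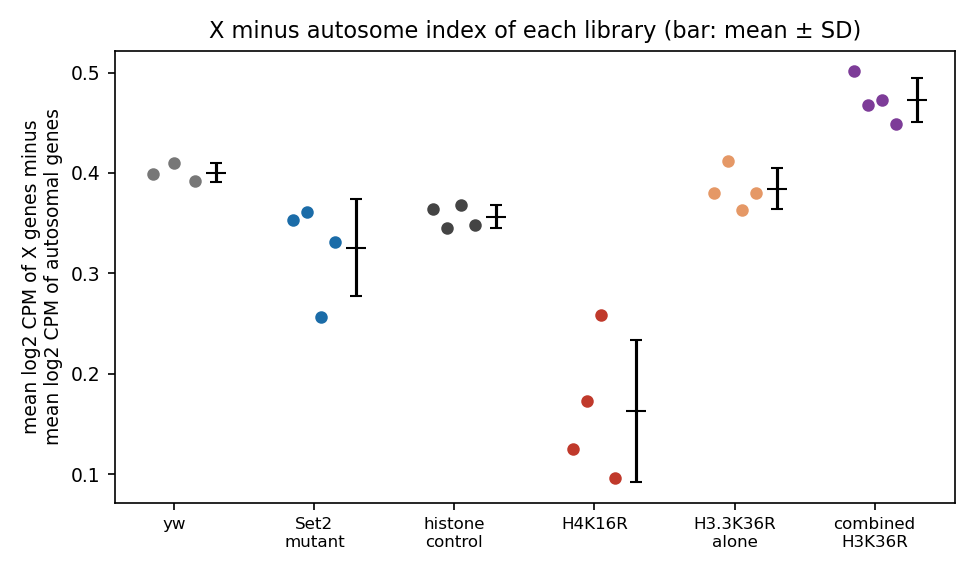
X minus autosome index of each library, as the mean log2 CPM of X genes minus that of genes on arms 2L, 2R, 3L and 3R, with a bar for mean ± SD in each genotype. The 4 H4K16R libraries lie at 0.0958 to 0.258, below every control library, and the 4 combined H3K36R libraries lie highest of all genotypes, at 0.448 to 0.501.

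Combined H3K36R larvae were compared with the histone control to ask what follows when H3.2 and H3.3 both lack lysine 36. Energy metabolism and growth genes were lower: 59 of 67 nuclear respiratory chain genes, 13 of 14 glycolysis genes and 18 of 22 genes of the nucleolus list fell. In these 3 lists only the nucleolar Non1 rose. Of listed Y-linked genes 5 of 7 were higher, and of genes of apoptosis and the p53 response 10 of 22. The calls of all 5 lists were lost with an estimated correlation (adjusted p = 0.289 to 0.75), while that of the whole Y arm held. In all, 5638 genes were called, 2361 higher and 3277 lower, with 630 higher and 1122 lower by at least 2-fold. Of these calls 41.88% were higher, but 45.9% with RLE size factors, 44.45% with TMM factors from autosomal genes and 46.13% with DESeq2. Libraries did not overlap for 42.6% of genes, where chance gives 2.86%.

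Among called genes of at least 5 mean CPM without overlap, the largest falls were in mfr, from 14.9 ± 3.03 to 0.141 ± 0.066 CPM (SD, n = 4 each; -6.73 ± 0.44, edgeR adjusted p = 1.19e-09). Next came the peptidoglycan recognition gene PGRP-SC1a (-3.96), the phosphatase gene Alp7 (-3.85), the gut trypsin gene thetaTry (-3.47 ± 0.24) and FucTC (-3.44 ± 0.14, adjusted p = 8.97e-13). Falls of this order were also seen in the cuticle genes Cpr67Fa1 (-3.27) and Lcp65Ag1 (-2.85) and the antimicrobial peptide gene Dro (-2.79). The call of Dro was lost without control replicate 2 or any of the combined H3K36R replicates (adjusted p = 0.06 to 0.0857). The largest rises in that set were in Jig (7.50 ± 1.11), in the Stellate-like gene SteXh:CG42398 on an unplaced scaffold (6.43 ± 0.78), in blanks, a testis-expressed RNA-binding gene (4.19 ± 0.25, adjusted p = 1.18e-10), in Marf1 (3.50), mamo (3.46), Myo81F (2.80), lncRNA:Irar (2.76) and Cyp4ac3 (2.72). The pigmentation gene y fell by 1.02 on the log2 scale (adjusted p = 3.04e-05), and w was at 0.14. Both were higher in the histone control than in yw, y at 37.3 against 2.62 CPM and w at 142 against 1.06 CPM. Alleles or marker copies of both genes in the stocks are not described in the sources used here.

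In the respiratory chain list (median -0.88) the genes ATPsynD (-1.08 ± 0.09), ATPsynCF6 (-1.01 ± 0.09), ND-B18 (-1.03 ± 0.09) and SdhD (-1.01 ± 0.09) fell alike, and 60 were lower adjusted over the list alone. The adjusted p was 2.86e-31, and the adjusted p = 0.289 with an estimated correlation. Of 28 mitochondrially encoded genes 10 fell and none rose, with mt:CoII at -1.17 and mt:CoI at -0.73 (adjusted p = 0.0153, and adjusted p = 0.916 with an estimated correlation). In glycolysis Gapdh2 (-0.89 ± 0.12) and Gpdh1 (-1.34 ± 0.18) fell (adjusted p = 3.67e-05, and adjusted p = 0.678 with an estimated correlation). In the nucleolus list (median -1.25) nop5 (-1.91 ± 0.21), Nop60B (-1.68) and nclb (-1.58) fell and Non1 rose (1.17 ± 0.14), at an adjusted p of 4.25e-09 and an adjusted p = 0.75 with an estimated correlation. Of 36 replication and cell cycle genes 22 fell, as Mcm6 (-1.33), Mcm2 (-1.39) and Orc2 (-1.92) did, and 2 rose, among them the cell cycle inhibitor gene dap (0.63 ± 0.08). These genes passed at an adjusted p of 0.00283 and an adjusted p = 0.916 with an estimated correlation. Oxidative stress and detoxification genes had 18 of 30 lower and 3 higher (18 and 4 adjusted over the list alone), among them Trxr1 (-1.05), Sod1 (-0.78) and Sod2 (-0.77). The list passed at an adjusted p of 0.00345 and an adjusted p = 0.916 with an estimated correlation. Ribosomal protein genes had 20 of 88 lower and 2 higher, and the list did not pass (adjusted p = 0.0683).

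Digestive enzymes of the midgut had 28 of 52 lower and 3 higher (30 and 4 adjusted over the list alone), including thetaTry, epsilonTry (-2.04), Jon99Fi (-2.76) and Jon65Ai (-2.58). Their adjusted p was 4.65e-06, and their adjusted p = 0.916 with an estimated correlation. Cuticle proteins had 36 of 115 lower and 5 higher, such as Cpr67Fa2 (-2.67) and Lcp65Aa (-1.95), with an adjusted p of 0.00976 and an adjusted p = 0.916 with an estimated correlation. Hemocyte genes had 7 of 16 lower and 3 higher, led by the basement membrane collagen genes Col4a1 (-1.29 ± 0.11) and vkg (-1.25 ± 0.11), with an adjusted p of 0.0446 and an adjusted p = 0.916 with an estimated correlation. Fat body genes had 12 of 23 lower, as the lipoprotein gene apolpp was (-1.89 ± 0.19), and 2 higher, among them the lipase gene bmm (1.36 ± 0.21), and the list did not pass (adjusted p = 0.0583).

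Genes of apoptosis and the p53 response had 10 of 22 higher and none lower, among them the DNA break repair genes rad50 (1.38 ± 0.13), nbs (0.47) and mre11 (0.53) and the cell death gene hid (1.24 ± 0.19). The list had an adjusted p of 0.000721 and an adjusted p = 0.289 with an estimated correlation. Polycomb group genes had 9 of 18 higher and 1 lower (10 and 1 adjusted over the list alone), as with Su(z)2 (1.07 ± 0.12) and Asx (0.46), at an adjusted p of 0.0394 and an adjusted p = 0.916 with an estimated correlation. The NSL complex holds the H4K16 acetyltransferase outside the MSL complex. Its list, which also counts the deacetylase genes Sirt1 and Sirt2, had 5 of 9 genes higher, led by Rcd5 (1.23 ± 0.11) and nsl1 (0.47), and wds lower (-1.13 ± 0.14). That list passed at an adjusted p of 0.0266 and an adjusted p = 0.686 with an estimated correlation, and it was not tested without Sirt1 and Sirt2. Among H3K36 factors ash1 (0.52) and MBD-R2 (0.45) rose with 1 other gene and none fell, and the list did not pass (adjusted p = 0.404).

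Y-linked genes are transcribed in males alone. Of 7 listed, 5 rose and 1 fell (median 4.45, adjusted p = 0.00433, and adjusted p = 0.289 with an estimated correlation). The dynein genes kl-2 (3.63 ± 0.55) and kl-3 (4.45 ± 0.78), needed in sperm, and WDY (5.31 ± 0.84) rose, and FDY fell (-1.44 ± 0.35). Levels were low, as for kl-2 at 2.72 ± 0.512 against 0.220 ± 0.097 CPM (SD, n = 4 each). Over all 43 tested genes of the Y arm 19 were higher and 1 lower, with a median of 2.46, and that call held with an estimated correlation (adjusted p = 0.00299).

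On the X, 441 genes were higher and 510 lower, that is 19.6% and 22.7% of X genes, against 15.9% and 22.9% of autosomal genes. The X minus autosome index was 0.472 ± 0.022 against 0.356 ± 0.011 (SD, n = 4 each), a shift of 0.12 ± 0.01 (exact permutation p = 0.0286, adjusted p = 0.0476). The shift came mainly from weakly expressed genes: it was 0.34 in the least expressed tercile of genes, 0.00 in the middle tercile and 0.06 in the highest tercile. Taken with the median log2 CPM over genes instead of the mean, the shift turned to -0.06 (exact permutation p = 0.0286). The median log2 fold change kept the direction, at 0.04 for X genes and -0.04 for autosomal genes, with 47.6% and 52.4% of them below 0. Over genes with at least 10 counts in every library it was 0.04 and did not pass after adjustment. With each arm set against all other tested genes, the X was at 0.11, 2R at -0.08 and 3R at -0.06. Each of these arms had exact permutation p = 0.0286 and adjusted p = 0.0714, so the X did not stand out from 2R and 3R by that test. The genes msl-3 (0.41 ± 0.09, adjusted p = 0.000975) and Clamp (0.37 ± 0.06) of the MSL list rose and none fell (2 of 10, adjusted p = 0.331). The roX1 RNA was at 0.35 ± 0.15 (adjusted p = 0.0673), which passed with RLE size factors (0.0449), with DESeq2 (0.0332) and without control replicate 4 (0.034). The roX2 RNA was at -0.42 ± 0.18 (adjusted p = 0.0629), which passed without control replicate 3 (0.0376).

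**Figure D3:**
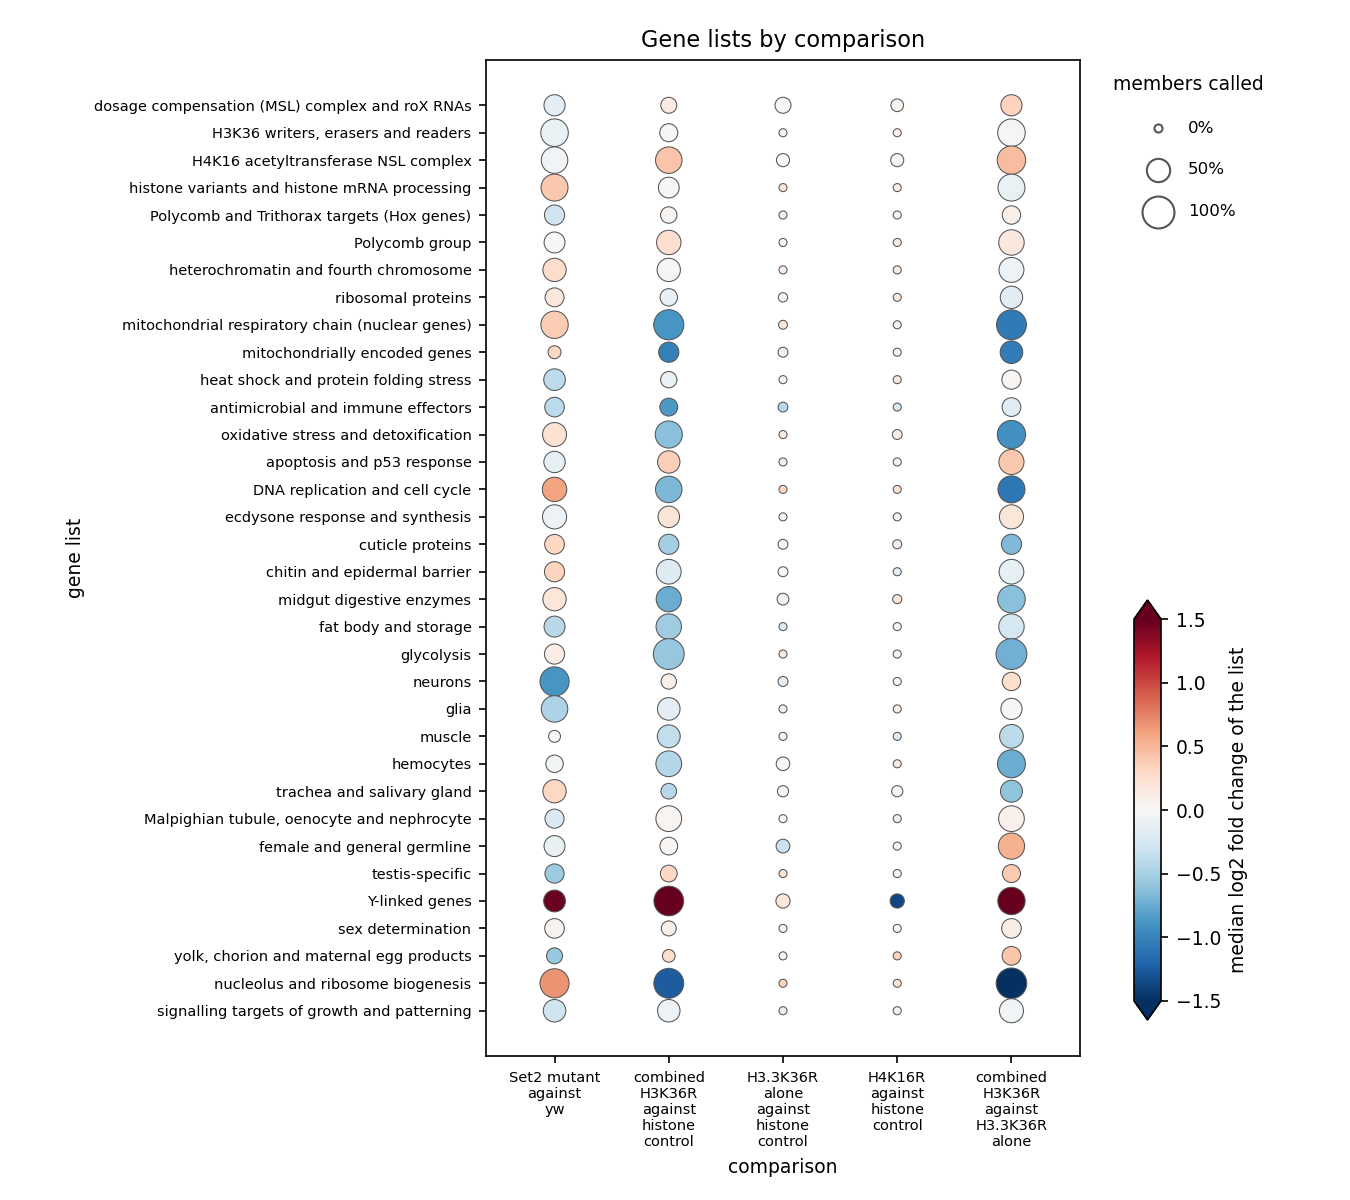
Median log2 fold change (colour) and share of members called (circle area) for 34 gene lists in the 5 comparisons. The median of the nuclear respiratory chain list is 0.38 in the Set2 mutant, -0.88 in combined H3K36R and -1.06 in combined H3K36R against H3.3K36R alone.

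H3.3K36R alone was compared with the same control to separate the part of H3.3. Far fewer genes were called, 282 in all, 136 higher and 146 lower. Both roX RNAs fell: roX1 from 1317 ± 187 to 773 ± 91.5 CPM (SD, n = 4 each; -0.77 ± 0.15, edgeR adjusted p = 0.00568) and roX2 from 111 ± 16.5 to 61.7 ± 7.07 CPM (-0.85 ± 0.18, adjusted p = 0.0104). The MSL list had those 2 of 10 genes lower and did not pass (adjusted p = 0.0598). The roX RNAs are made in males, and the share of males in the pools is not known in any genotype. A lower share of males in H3.3K36R alone was not tested and cannot be told apart from an effect of the mutation on these RNAs. Among called genes of at least 5 mean CPM without overlap, the largest falls were in mfr (-6.64 ± 0.44) and FucTC (-3.67 ± 0.15, adjusted p = 3.21e-13). The largest rise in that set was in the glucuronosyltransferase gene Ugt35C1 (6.51-fold, adjusted p = 7.47e-09).

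Other rises in that set were in Ugt35E2 (1.44), gNacalpha (1.33), Ugt302E1 (1.25), Cpr12A (1.21), Arc42 (1.09), Psf3 (0.98) and Uch (0.97). Other falls in it were in the cuticle genes TwdlL (-2.02 ± 0.34), Edg91 (-1.34) and Ccp84Ag (-1.27), the antimicrobial gene Listericin (-1.98), the lipase gene mag (-1.58) and the protease gene Ser6 (-1.41). The calls of Cpr12A, Uch and Listericin were lost without any of the control replicates 1, 2 and 4 or H3.3K36R replicates 3 and 4 (adjusted p = 0.055 to 0.199). That of Uch was also lost without H3.3K36R replicate 2 (0.0568) and that of Listericin without replicate 1 (0.0589). Psf3 lost its call without control replicate 1 (adjusted p = 0.0629) or 2 (adjusted p = 0.0563), and Ccp84Ag without control replicate 1 (adjusted p = 0.0629) or H3.3K36R replicate 4 (adjusted p = 0.0541).

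Germline genes had 3 of 23 lower and none higher (8 lower and 1 higher adjusted over the list alone). The 3 were piwi (-0.86 ± 0.16), bgcn (-1.01 ± 0.24) and vas (-0.70 ± 0.18), which act in germ cells, piwi also in silencing of transposons. The list passed at an adjusted p of 0.000274 and stood at an adjusted p = 0.289 with an estimated correlation. The bgcn call was lost without any of the control replicates 1, 2 and 4 or H3.3K36R replicates 1, 3 and 4 (adjusted p = 0.05 to 0.103). The vas call was lost without control replicate 1 (adjusted p = 0.123) or 4 (adjusted p = 0.106) or H3.3K36R replicate 2 (adjusted p = 0.0633) or 4 (adjusted p = 0.0858). Another 7 lists passed against other genes although at most 4 of their members were called. The respiratory chain (1 of 67 higher, ND-MLRQ at 0.60 ± 0.10), replication (0 of 36) and the nucleolus (0 of 22) had medians of 0.19, 0.31 and 0.33. They passed at adjusted p of 0.000115, 0.00283 and 0.00855, each with an adjusted p = 0.916 with an estimated correlation. Immune effectors (1 of 30 lower, Listericin), midgut enzymes (3 lower and 1 higher of 52), fat body (0 of 23) and neurons (1 of 28 lower, the tyrosine hydroxylase gene ple at -0.64 ± 0.12) had medians of -0.42, -0.09, -0.22 and -0.16. Their adjusted p were 0.00209, 0.00645, 0.0211 and 0.00304, with an adjusted p = 0.916 with an estimated correlation except for fat body (0.885). At low expression the salivary glue gene Sgs5 rose from 0.0217 to 2.17 CPM (6.67 ± 0.81). The hemocyte gene Hml rose (0.52 ± 0.10).

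On the X 37 genes were higher and 48 lower, that is 1.65% and 2.13% of X genes, against 0.819% and 0.802% of autosomal genes. The index, which nets both directions, does not show this, and its shift of 0.03 ± 0.01 did not pass (exact permutation p = 0.0857, adjusted p = 0.0857). It passed at 0.03 over genes of at least 10 CPM and over protein-coding genes, and at 0.04 once the length trend was removed, and turned to -0.01 with the median log2 CPM over genes. The H3.3 gene His3.3B lies on the X, as Set2 does. Differences between the X chromosomes of the stocks were not tested. For H3.3K36R alone, combined H3K36R and the Set2 mutant they cannot be told apart from effects of the mutations on X genes. Arm 4 had 2 of 111 genes lower and none higher (median -0.10, adjusted p = 0.00144, and adjusted p = 0.918 with an estimated correlation). The number of called genes depended on the setting: it was 714 with DESeq2, 854 with the replicate number as a block (601 higher and 253 lower) and 989 without the third replicates (747 higher and 242 lower). It was 156 without control replicate 1, 184 without control replicate 2, 458 without H3.3K36R replicate 1, and 168 and 169 without H3.3K36R replicates 3 and 4. The 4 libraries of H3.3K36R spread from -35.1 to 44.5 on the main axis of spread within genotypes and those of the control from -45.2 to 28.6.

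H4K16R larvae served as the reference for a loss of dosage compensation, since acetylated H4K16 marks the compensated male X. X-linked genes were lower as a class: of the 188 genes called, 117 of 148 lower genes lay on the X and 2 of the 40 higher genes did. On the X 5.20% of genes were lower, against 0.253% on the autosomes, and 72.4% of X genes had a negative log2 fold change, against 35.7% of autosomal genes. Adjusted over the X genes alone, 261 were lower and 7 higher. The index was 0.163 ± 0.071 against 0.356 ± 0.011 (SD, n = 4 each), a shift of -0.19 ± 0.04 or -12.6% (exact permutation p = 0.0286, adjusted p = 0.0476), with every H4K16R library below every control library. The X arm passed against all other genes at an adjusted p of 9.52e-20 and kept its call with an estimated correlation (adjusted p = 2.61e-05). The shift was -0.13, -0.24 and -0.21 in the lowest, middle and highest tercile of genes by expression. Exact permutation p was 0.114, 0.0286 and 0.0286 for these, not adjusted. In the permutation test of arms the X was at -0.19 and 3R at 0.05, each with exact permutation p = 0.0286 and adjusted p = 0.0714.

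**Figure D4:**
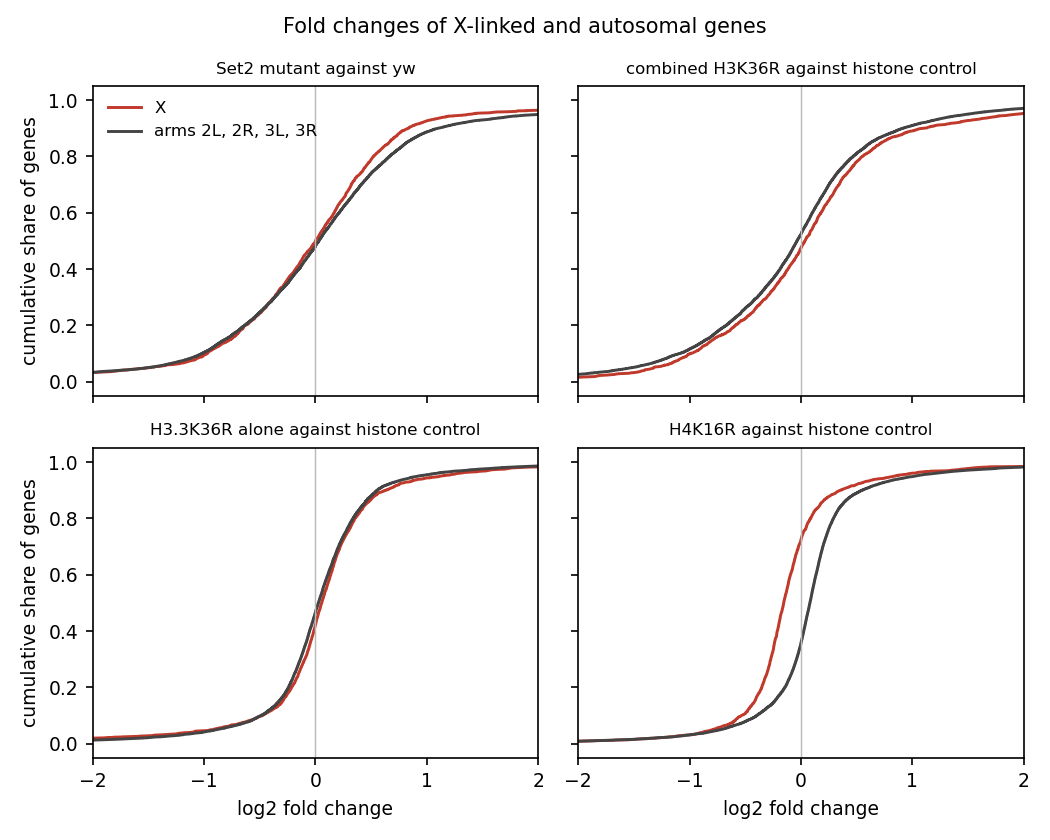
Cumulative share of genes by log2 fold change for X-linked genes (red) and genes on arms 2L, 2R, 3L and 3R (grey) in 4 comparisons. In H4K16R 72.4% of X genes lie below 0 against 35.7% of autosomal genes.

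The roX RNAs did not pass in H4K16R (roX1 at -0.19, adjusted p = 0.6; roX2 at -0.09, adjusted p = 0.861), and of the MSL list only mof fell (-0.41 ± 0.10, adjusted p = 0.0443). The mof call was lost without control replicate 1 (0.0774) or 4 (0.156) or H4K16R replicate 1 (0.139), 2 (0.0527) or 4 (0.0717). Among called genes of at least 5 mean CPM without overlap, the largest rises were in toy, an eye development gene on arm 4 (0.97 ± 0.09, adjusted p = 2.89e-06), the kinetochore gene Spc105R (0.89), w (0.79, from 142 to 245 CPM), mip120 (0.56), Tcs3 (0.55), Dpck (0.50), Brd7-9 (0.48) and MBD-like (0.46). The largest falls in that set were in the cuticle genes TwdlL (-2.09 ± 0.34, adjusted p = 0.00466) and TwdlN (-1.04), in Cyp4d14 (-0.94), PK2-R2 (-0.81), the maltase gene Mal-A5 (-0.81 ± 0.14), ldd (-0.79), Spn47C (-0.72) and Tsp42Ei (-0.71). The marker gene w was at 1.06 CPM in yw, and alleles or marker copies of w in the histone stocks are not described in the sources used here. Its rise may therefore not be one of the native X-linked gene, which was not tested. Without control replicate 1 the calls of mip120, Tcs3, MBD-like, TwdlN, Cyp4d14 and PK2-R2 were lost (adjusted p = 0.063 to 0.161). All of these but Tcs3 were also lost without H4K16R replicate 1 (0.0529 to 0.155), all but MBD-like and Tcs3 without control replicate 4 (0.0624 to 0.16), and TwdlN, Cyp4d14, PK2-R2 and MBD-like without H4K16R replicate 4 (0.0605 to 0.0968). The same held for mip120 and MBD-like without control replicate 2 (0.0601 and 0.121), for MBD-like, TwdlN and Cyp4d14 without control replicate 3 (0.0519 to 0.0677), and for MBD-like and PK2-R2 without H4K16R replicate 2 (0.0634 and 0.052) or 3 (0.098 and 0.0601).

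No gene list other than chromosome arms had more than 2 members called over all genes in H4K16R, and 4 lists passed against other genes. Ribosomal proteins (0 of 88 called, median 0.15, adjusted p = 1.36e-06) and replication (0 of 36, and 1 higher adjusted over the list alone; median 0.24, adjusted p = 0.00855) lay above other genes, each with an adjusted p = 0.916 with an estimated correlation. Muscle (0 of 25, median -0.21, adjusted p = 0.000115) lay below, with an adjusted p = 0.916 with an estimated correlation. Chitin and barrier genes (0 of 28) had a median of -0.14 and a test for lower values (adjusted p = 0.00876, and adjusted p = 0.898 with an estimated correlation) but a mean of 0.22. The number of called genes depended on the setting: it was 399 with factors from autosomal genes (37 higher and 362 lower), 656 with DESeq2, 321 with protein-coding genes alone, 311 with the length trend removed, and 615 with the axis covariate. It was 9 with a fit of these 8 libraries alone. Without 1 library it was 80, 312 and 81 (control replicates 1, 2 and 4) and 71, 480 and 112 (H4K16R replicates 1, 3 and 4). H4K16R replicate 3 scored 85.6 on the main axis of spread within genotypes and the other H4K16R libraries -47.0 to -34.6.

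Combined H3K36R was compared with H3.3K36R alone to isolate the mutation of H3.2. This gave 6858 called genes, 2835 higher and 4023 lower. The balance depended on the scaling: 41.34% of calls were higher, but 47.85% with RLE size factors, 46.1% with TMM factors from autosomal genes and 48.12% with DESeq2. Cuticle, hemocyte, Polycomb group and NSL genes, whose lists passed against the control, did not pass here (adjusted p = 0.0517, 0.0581, 0.176 and 0.0764), though hemocyte genes did with the replicate block (adjusted p = 0.0496). Germline and neuronal genes passed here and not in combined H3K36R against the control (adjusted p = 0.191 and 0.425 there). Whether these lists differ between both comparisons was not tested. The roX1 RNA was higher by 1.12 ± 0.15 (edgeR adjusted p = 2.78e-06), at 1678 ± 217 against 773 ± 91.5 CPM (SD, n = 4 each). The roX2 RNA was at 0.43 ± 0.18 (adjusted p = 0.0504), which passed with RLE size factors (0.0216), with factors from autosomal genes (0.0277) and with DESeq2 (0.0125). The MSL list had 4 of 10 genes higher and none lower (5 adjusted over the list alone), with msl-3 (0.46), msl-2 (0.39) and Clamp (0.36) beside roX1, and did not pass (adjusted p = 0.0738). A difference in the share of males between these pools was not tested for the roX RNAs here either.

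Among called genes of at least 5 mean CPM without overlap, the largest rises were in Jig (6.80 ± 1.07), SteXh:CG42398 (4.63), mamo (3.60), lncRNA:Irar (3.29), Cyp4ac3 (3.06), Myo81F (2.94), the sterol-binding gene Npc2c (2.73) and Marf1 (2.63). The largest falls in that set were in the phosphatase genes Alp7 (-5.44 ± 0.94) and Alp8 (-3.50), the lysozyme gene LysB (-3.63), PGRP-SC1a (-3.56), Lcp65Ag1 (-3.49), thetaTry (-3.13), the antifungal peptide gene Drsl2 (-3.06) and PH4alphaMP (-2.87).

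Respiratory chain genes had 58 of 67 lower and none higher (59 and 2 adjusted over the list alone; median -1.06, adjusted p = 2.14e-32, and adjusted p = 0.289 with an estimated correlation). Mitochondrially encoded genes had 13 of 28 lower and none higher (adjusted p = 0.0153, and adjusted p = 0.916 with an estimated correlation). Glycolysis had 13 of 14 lower (adjusted p = 9.2e-06, and adjusted p = 0.619 with an estimated correlation). The nucleolus had 19 of 22 lower, with nop5 at -2.14 ± 0.21 and NHP2 at -2.22 ± 0.23, and Non1 higher at 1.52 ± 0.14 (adjusted p = 4.17e-10, and adjusted p = 0.75 with an estimated correlation). Replication had 23 of 36 lower and 2 higher, with Orc2 at -2.48 ± 0.26 and Mcm7 at -2.04 ± 0.26 (adjusted p = 0.000101, and adjusted p = 0.916 with an estimated correlation). Detoxification had 20 of 30 lower and 3 higher (adjusted p = 0.00489), and midgut enzymes 29 of 52 lower and 9 higher (adjusted p = 0.00876), each with an adjusted p = 0.916 with an estimated correlation. Apoptosis genes had 13 of 22 higher and none lower, led by rad50 (1.54 ± 0.13; adjusted p = 0.000721, and adjusted p = 0.289 with an estimated correlation). Germline genes had 13 of 23 higher and 2 lower, with the piRNA pathway genes krimp (2.60 ± 0.19) and qin (1.08 ± 0.15) among the higher (adjusted p = 0.0059, and adjusted p = 0.619 with an estimated correlation). Neurons had 7 of 28 higher and 1 lower (adjusted p = 0.0394, and adjusted p = 0.919 with an estimated correlation). Y-linked genes had 4 of 7 higher and 1 lower (adjusted p = 0.0488, and adjusted p = 0.503 with an estimated correlation), a call that was also lost with the replicate block (adjusted p = 0.0856). Over the 43 genes of the Y arm the call held with an estimated correlation (20 higher, 1 lower, adjusted p = 0.0192).

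On the X 480 genes were higher and 602 lower, and the index shift was 0.09 ± 0.02 (exact permutation p = 0.0286, adjusted p = 0.0476). With the median log2 CPM over genes it was -0.06 (exact permutation p = 0.0857), while the median log2 fold change was 0.02 for X genes and -0.04 for autosomal genes. The shift did not pass over genes of at least 10 CPM (0.01) or with 10 counts in every library (0.02). It was 0.31 in the least expressed tercile of genes, -0.00 in the middle tercile and 0.02 in the highest tercile. In the permutation test of arms the X was at 0.08, 3L at 0.03, 2R at -0.08, 3R at -0.07 and arm 4 at 0.20. Each of these arms had exact permutation p = 0.0286 and adjusted p = 0.0714.

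The effects of the Set2 mutant and of combined H3K36R were set side by side because Set2 methylates H3K36. Fewer genes changed in the same direction than independent calls would give, 620 (234 higher and 386 lower) against 1245.4, and more changed in opposite directions, 2522 against 1266. Of the latter 1589 were higher in the Set2 mutant and lower in combined H3K36R, among them ATPsynCF6 at 0.92 and -1.01, and 933 the reverse, among them Pdcd4. The 620 genes changed in the same direction included Jig (7.49 and 7.50) and FucTC (-2.58 and -3.44), named above among the largest changes of both comparisons. Across the 14365 genes, which are not independent replicates, Pearson's r was -0.14 and Spearman's rho -0.29. On the main axis of spread within histone genotypes the Set2 libraries lay at 52.8 to 70.4 and those of combined H3K36R at -49.3 to -15.2, against -12.2 to -5.92 in yw and -45.2 to 28.6 in the histone control. With the axis score as a covariate, 486 genes changed in the same direction, against 705.7 for independent calls, and 1208 in opposite directions, against 677.3. Pearson's r was then -0.05 and Spearman's rho -0.16. A test of the difference between both effects called 7404 genes, 4015 of them with the higher effect in the Set2 mutant, and 5575 with the axis covariate. The effects on the X index differed by -0.19 (exact permutation p = 0.000816 over 2450 relabelings), and by -0.03 with the median over genes (p = 0.698). Labels were permuted within both backgrounds at once. These p-values are therefore against no effect in either genotype, and do not test whether both effects are equal.

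**Figure D5:**
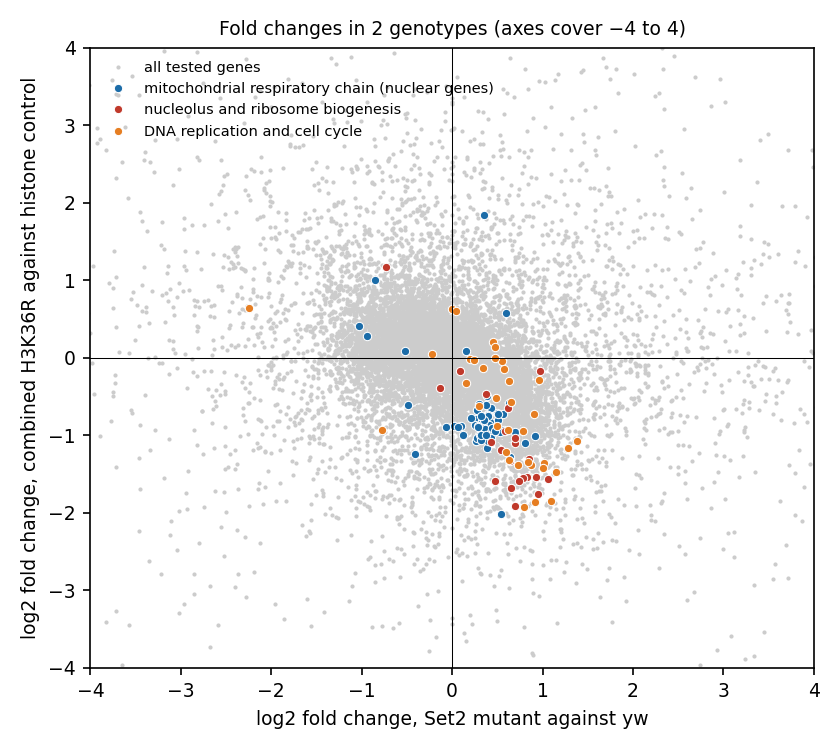
Log2 fold change of each gene in the Set2 mutant against yw (horizontal axis) and in combined H3K36R against the histone control (vertical axis), with genes of 3 lists coloured and all tested genes in grey; values outside -4 to 4 are not drawn. Most genes of the 3 lists lie to the right of and below 0.

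Combined H3K36R and H3.3K36R alone shared a control group, so their overlap was set against regroupings of control libraries. They had 129 genes changed in the same direction (55 higher and 74 lower) and 37 in opposite directions, against 55.7 and 55 for independent calls. When each effect was measured against different control libraries, 56 to 82 genes were shared, against 14.4 to 40.0 for independent calls. The genes mfr and FucTC fell in both genotypes and stood at -0.09 and 0.22 between them without passing. Combined H3K36R and H4K16R had 45 genes changed in the same direction, against 40.3 for independent calls, and 51 in opposite directions, against 33.4. These effects share the control as well. Against different control libraries, at most 4 genes changed in opposite directions in 5 of the 6 regroupings, against 1.6 to 4.4 for independent calls, and 48 against 18.9 in the other. The excess of opposite changes therefore did not hold in most regroupings. Changes in the same direction were 5 to 11 in those 5, against 1.6 to 5.5 for independent calls and above that number in each, and 14 against 24.1 in the other. A test of the difference between these 2 effects called 6488 genes, 2635 of them higher in combined H3K36R, and the X index differed by 0.31 (exact permutation p = 0.0286).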

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

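The tests of fewer males and of a single library behind the X-linked change in H4K16R, and the corrections for gene length and for the axis of spread, were chosen after the results were seen, and the other tests in this part before.

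In the tests for a library apart from the rest of its group, 80 groups of 4 values were examined and 3 were found, where chance gives about 1 in 20, or 4. In Set2 replicate 3 roX2 was at 86.6 CPM, against 54.1 to 58.8 in the other Set2 mutant libraries. In control replicate 4 mle was at 59.0 CPM, against 53.5 to 54.3 in the other control libraries. In H3.3K36R replicate 1 mle was at 51.8 CPM, against 59.4 to 60.5 in the other libraries of that genotype.

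The X minus autosome shift differed between the Set2 effect and the combined H3K36R effect by -0.19 (-0.191, exact permutation p = 0.000816). That p is against no effect in either genotype, so it does not test whether both effects are equal. With the median log2 CPM over genes that difference was -0.0255 and did not pass (exact permutation p = 0.698), and the combined H3K36R shift was largest in the least expressed tercile of genes (0.34). The shift differed between combined H3K36R and H4K16R by 0.31 (0.309; exact permutation p = 0.0286). The Set2 effect and the combined H3K36R effect differed by test in 7404 genes, and combined H3K36R and H4K16R in 6488 genes.

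Other splits of the same libraries bear on whether chance can be excluded for the gene counts. In each comparison 1 of the 35 splits, the real one, called as many genes at an adjusted p below 0.05. That is the smallest share that 35 splits can give, and by this count it argues against chance. The real and the highest other counts were 6399 and 4078 for the Set2 mutant, 5638 and 0 for combined H3K36R (edgeR; DESeq2 was not run on the splits; at an unadjusted p below 0.05 the real split had 6624 genes and the others 98 to 3910), 282 and 35 for H3.3K36R alone, 188 and 79 for H4K16R, and 6858 and 2009 for combined H3K36R against H3.3K36R alone. Counted at an unadjusted p below 0.05, the real split did not lead for H3.3K36R alone, with 2914 genes against 3701 in 1 other split. Nor did it for H4K16R, with 2132 genes against 2175 to 2300 in 4 other splits, so by that count chance is not excluded for these 2 comparisons. The real split led by that count in the other comparisons, so only there do both counts argue against chance. For the differences between effects the real split was again the 1 that called as many genes, with 7404 against at most 3623 in 100 drawn splits for the Set2 and combined H3K36R effects, and 6488 against at most 671 in 35 splits for combined H3K36R and H4K16R.

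The fall of X-linked genes in H4K16R is what loss of H4K16 acetylation on the male X would give. That account was not tested, since acetylation was not measured here and the sexes were pooled, and 3 other explanations were weighed. The middle tercile of genes by expression had a shift of -0.24 (exact permutation p = 0.0286). That argues against a change in weakly expressed genes alone or in strongly expressed genes alone. The tercile nearest to 0, the lowest, had a shift of -0.13 (-0.128 ± 0.052, SE) that did not pass (exact permutation p = 0.114). Whether the change reaches weakly expressed genes therefore stays open. A single library is argued against, since the smallest share of the shift kept with 1 library left out was 0.887. For fewer male larvae in the H4K16R pools, the mean log2 fold change of roX1 and roX2, which are made in males, was compared with the X shift and exceeded it by 0.054 ± 0.115 (SE). That test decides nothing, since the X of control males is compensated and the X index need not follow the share of males as the roX RNAs do. With a compensated male X a lower share of males alone would not be expected to lower the index. The value also rests on H4K16R replicate 3, with roX1 at 792 CPM against 1129 to 1397 in the other 3 libraries. Without it roX1 was at -0.081, roX2 at 0.02 and the shift at -0.228. No sex counts of the pools are given in the sources used here, so the share of males stays unknown.

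Nuclear genes of the respiratory chain were higher in the Set2 mutant and lower in combined H3K36R, part of the difference in 7404 genes, and 2 technical explanations were weighed beside the genotypes. Gene length bias between libraries is argued against as the whole cause: with each library's trend on gene length removed, 0.805 ± 0.146 (SE) of the median was kept in the Set2 mutant (0.38 to 0.31) and 0.863 in combined H3K36R (-0.88 to -0.76). Position on the axis that separates replicate libraries within the histone genotypes is open for the Set2 mutant, where 0.549 ± 0.136 of the median was kept (0.38 to 0.21, with 21 of 67 genes still called higher). In combined H3K36R 0.936 of the median was kept on that axis, with 59 of 67 genes lower. That axis may hold developmental age within the L1 stage, which the labels do not give, and this was not tested.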

How the results depend on the processing

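Removal of the length trend, the axis covariate and leaving out the third replicates were chosen after the results were seen, and the other alternatives before. Across the alternatives 155 values kept their direction and call or stayed within 1.5 times of the count, 34 moved, 4 passed where they had not, 6 no longer passed and 2 reversed. Except where a cause is named, the cause was not tested. Called genes in the Set2 mutant were 3329 with the axis covariate and 4867 to 6333 with 1 library left out. For combined H3K36R they were 4775 to 5542 with 1 library left out, and against H3.3K36R alone 6071 to 6910. For H3.3K36R alone they were 714 with DESeq2, 854 with the replicate block, 989 without the third replicates and 156 to 458 with 1 library left out. For H4K16R they were 399 with TMM factors from autosomal genes (9.27% of them higher, against 21.3%), 656 with DESeq2, 321 over protein-coding genes, 311 with the length trend removed, 615 with the axis covariate, 9 with only the compared groups in the fit, which has fewer libraries to estimate spread, and 71 to 480 with 1 library left out.

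The X shift of combined H3K36R reversed with the median log2 CPM over genes (-0.061), and so did that against H3.3K36R alone (-0.0554), beside a larger shift among weakly expressed genes in both. Median log2 fold changes kept the direction, at 0.0356 for X and -0.0365 for autosomal genes in the first and 0.0214 and -0.0433 in the second. Over genes with 10 counts in every library, which drops weakly expressed genes, these shifts were 0.0431 and 0.0187, and over genes of at least 10 CPM the second was 0.0124. As differences of mean edgeR log2 fold changes they were 0.141 and 0.114. With 1 library left out they were 0.106 to 0.121 and 0.0777 to 0.0979. For the Set2 mutant the shift was -0.0878 and passed with a prior count of 0.5, and was -0.0865 to -0.0512 with 1 library left out. For H3.3K36R alone it was -0.0056 with the median, passed at 0.0303 (at least 10 CPM), 0.0293 (protein-coding genes) and 0.0372 (length trend removed), and was 0.0181 to 0.0348 with 1 library left out. For H4K16R it was -0.270 with the median and -0.210 with 10 counts in every library; p stayed at 0.0286, the smallest possible, and the adjusted value missed because fewer of the 5 comparisons reached it. With 1 library left out it was -0.228 to -0.172. The difference between the Set2 and combined H3K36R shifts was -0.0255 with the median (exact permutation p = 0.698).

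Of the 46 list calls by camera, 0 passed with an estimated correlation, 45 passed with the replicate block (all but Y-linked genes in combined H3K36R against H3.3K36R alone, adjusted p = 0.0856) and 34 in fry's test of direction; fry called 61 by direction and 125 in either direction. Of the 5 arm calls 3 passed with an estimated correlation; fry called 17 by direction and 35 in either direction. At an adjusted p below 0.01, 291, 69 and 9 genes were shared in direction by combined H3K36R with the Set2 mutant, H3.3K36R alone and H4K16R. With control libraries split between both effects, the median was 63 for H3.3K36R alone and 8 for H4K16R. Among named genes 3 reversed, all in the Set2 mutant with the length trend removed: cnc (adjusted p = 0.653), Mef2 (0.862) and Msp300 (0.0236). Removing that trend also moved the median log2 fold change over all genes by 0.154 in combined H3K36R against H3.3K36R alone, by 0.117 against H4K16R and by -0.116 in the difference of the Set2 effect from it. Against the histone control it moved by 0.089. After removal of group means, replicates 1 and 3 correlated best with their own number in all 4 comparisons of histone genotypes (0.142 to 0.432). Replicate 2 did so in none of them (-0.004 to 0.06), replicate 4 in some (-0.037 to 0.114), and the Set2 mutant with yw for replicate 2 alone (-0.001 to 0.045). The labels do not say that equal numbers were collected together, so they were used as a block only as an alternative. With 111138070 counts or more per library, depth limits mainly genes near the filter, such as Y-linked genes.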

Other observations

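The test of more males behind the Y-linked change was chosen after the result was seen, and that of the detection floor before. Among gene lists not yet described, none passed against other genes in the Set2 mutant or in combined H3K36R. Histone variants and histone mRNA processing had 6 of 13 genes higher and 3 lower in the Set2 mutant, among them the centromere histone gene cid (2.03 ± 0.52) and the histone mRNA factor gene Slbp (0.43 ± 0.12). In combined H3K36R 3 were higher, including the H3.3 chaperone gene Daxx (0.65 ± 0.09) and His4r (0.46 ± 0.09), and 2 lower, including Lsm11 (-1.04 ± 0.26). Hox genes and other Polycomb targets had 5 of 14 lower and none higher in the Set2 mutant, led by pb (-0.86 ± 0.12), and in combined H3K36R Abd-B was higher (0.67 ± 0.11) and 2 were lower. Heterochromatin factors had 4 of 12 higher and 2 lower in both genotypes, in part with opposite signs: Su(var)3-9 was at 0.52 ± 0.15 and -0.95 ± 0.14, and the piRNA cluster gene del at -0.75 ± 0.17 and 0.90 ± 0.16. Ecdysone genes had 5 of 24 higher and 8 lower in the Set2 mutant, where ftz-f1 fell (-0.94 ± 0.21) and ImpE1 rose (3.06 ± 0.73). In combined H3K36R 8 were higher and 2 lower, with Eip74EF (1.78 ± 0.19) and the receptor gene EcR (0.62 ± 0.11) higher and the ecdysone synthesis gene spok lower (-1.11 ± 0.16).

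Tracheal and salivary gland genes had 6 of 16 higher and 2 lower in the Set2 mutant and 3 lower in combined H3K36R, led by dysf (-1.14 ± 0.10). Genes of Malpighian tubule, oenocytes and nephrocytes had 5 of 16 lower and none higher in the Set2 mutant, where the potassium channel gene Irk1 (-0.75 ± 0.10) and the nephrocyte slit diaphragm genes sns (-0.71 ± 0.11) and kirre (-0.75 ± 0.15) fell. In combined H3K36R 4 were higher and 6 lower, and kirre rose (0.71 ± 0.14). Testis-specific genes had 2 of 22 higher and 5 lower in the Set2 mutant, led by topi (-1.89 ± 0.33), and 4 higher and 1 lower in combined H3K36R. Sex determination genes had 3 of 18 higher and 3 lower in the Set2 mutant and 1 higher and 2 lower in combined H3K36R, where dsx fell (-1.18 ± 0.21). Yolk, chorion and maternal egg products had 4 of 20 lower in the Set2 mutant and 2 higher in combined H3K36R, where smg was at -0.59 ± 0.10 and 0.39 ± 0.09. The marker gene w was read at 0.536 and 1.06 CPM in the Set2 mutant and yw and at 142 to 245 CPM in the histone genotypes.

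Y-linked genes were higher in combined H3K36R, and 2 explanations were weighed. For a larger share of male larvae, the median of the 43 Y-linked genes (2.46) was compared with the log2 fold change of roX1 (0.35), the higher of the roX RNAs. It exceeded that value by 2.115 ± 0.505 (SE), an SE that takes the Y-linked genes as independent of each other. In H3.3K36R alone roX1 was at -0.77 and roX2 at -0.85, which cannot be told apart from a lower share of males there. Whether the roX RNAs follow the share of males in these genotypes is therefore not known. The test argues against a larger share of males only if combined H3K36R itself leaves the roX RNAs unchanged. A rise shared by all genes near the detection floor is argued against, since the Y-linked median was at percentile 100 of 10000 random lists matched on control expression, whose medians ran from -0.75 to 1.63 around 0.52. The testis-specific list did not pass (adjusted p = 0.378), and no biological explanation of the rise was tested. A difference between the Y chromosomes of the stocks, which the sources used here do not describe, stays open.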
